A study of Arabidopsis thaliana with 23 samples.

How the data were processed

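GFP-tagged REF6 proteins and the H3K27me3 mark were profiled by chromatin immunoprecipitation with sequencing in unopened flowers of 5-week-old Col-0 background plants grown at 22 °C by day and 20 °C at night, per the labels. Samples were grouped by their titles into 10 groups, and 15 of the 23 samples belong to the 6 groups with a peak list. The other 8 samples (input DNA of plants expressing GFP alone, and histone H3 of the wild type and the triple mutant) were not analysed here. The genotype entry of the REF6-ZnF samples in ref6 disagrees with their titles, and the titles were followed. The labels do not say that the samples of a group came from separate plants.

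The submitters' processing notes name Bowtie 1.1.2, Picard 2.60, MACS2 2.1.0, deepTools and the TAIR10 build, without their order or settings. The deposited lists, 4 of narrow REF6 peaks and 2 of broad H3K27me3 domains, have no header, and their columns were read in the order MACS2 writes. Peak names in the deposited lists hold the word pooled, so each list was taken as 1 call on the pooled samples of a group. The deposited score of a peak equals 10 times its −log10 p in the REF6 lists and 10 times its −log10 q in nearly all H3K27me3 domains, as checked on the values, and it was not used further. The deposited fold enrichment is a linear ratio of the pooled sample to a control chosen by the authors, and which input was the control is not given in the sources used here. The −log10 p and −log10 q of each peak are the authors' values as deposited. Summit positions are those of the deposited REF6 lists. Peak numbers in the names have gaps: 49.5% of the numbers were kept in REF6-GFP with DSG, 47.8% without DSG, 19.9% in REF6-ZnF-GFP in ref6, 36.4% in REF6-ZnF-GFP in the triple mutant, 98.6% in wild-type H3K27me3 and 98.7% in triple mutant H3K27me3. The rule that removed peaks is not given in the sources used here. In the H3K27me3 lists, 604 wild-type and 564 triple mutant domains have a q above 0.05. The read depth of the samples is not used here, and lists from libraries of unequal depth can differ in length for that reason alone.

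Gene names and positions came from a RefSeq gene table of the assembly TAIR10.1, and coordinates printed in the text are those of the deposited lists. The table has no exons and no sequence. It was used for names and for which genes a peak overlaps or neighbours. REF6-GFP summits with DSG fell in genes more often unshifted than at any shift tried, on all 5 chromosomes (83.6 to 87.0% unshifted, and a mean of 60.6 to 66.4% at shifts of 20 kb). The analysis covered 27444 protein-coding genes of the 5 nuclear chromosomes, and all 172 members of the 13 gene lists were matched by identifier.

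Peaks were counted as shared where they overlapped by at least 1 bp. Each share was compared with 1000 random placements of the peaks on their own chromosome without overlap (bedtools 2.31.1, fixed seeds), in a one-sided test for a share as high. The p-value counts the observed value among the placements. It is called exact because it uses no fitted distribution, although the placements were drawn at random and not enumerated, and it cannot be lower than 0.001. Lower-tail values were added after the data were seen. Summits were classed as inside a coding gene, within 1 kb of one, or farther away. A gene was bound where a summit lay in its body or within 1 kb on either side. A gene was marked where domains covered at least 50% of its body and unmarked where they covered less than 10%, and genes that were neither gained, lost, marked in both nor unmarked in both were called intermediate. Gene lists were compared with 10000 random lists of genes from the same of 10 length classes, two-sided, with Benjamini-Hochberg adjustment over 52 tests at a threshold of 0.05. Bootstrap intervals drew blocks of 1 Mb (for peak widths, single peaks) with replacement 1000 times. The p-value of a gene list was formed like that of the placements, and the smallest these lists can give is 0.0002. Gene families were compared with the other genes by a one-sided exact hypergeometric test.

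The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, apart from those said to be added later. The rule takes any list member, the 10 genes with a symbol and the highest fold in each REF6 list, the 10 gained and the 10 lost genes with the highest mean domain fold, and the 10 gained and bound genes with the highest REF6-GFP fold. The plan also held a test of a REF6 sequence motif, which was not run because no genome sequence was used here. Planned classes by untranslated region, exon and promoter were replaced by gene body and distance, and planned windows upstream of genes by windows on both sides, because the table was used without strand and exons.

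The tests of list overlap, odds ratios, gene lists and gene families were tested on simulated data, and those of summits in genes or domains and of the chromosome 4 position were not. With 0, 20 and 50% of 4526 peaks copied from the other list, the mean recovered share was 0.0962, 19.9 and 50.1% over 20 simulations. Simulated odds ratios of 1, 3 and 6 over 19449 genes gave means of 0.989, 3.03 and 6.03. A gene list of 20 with 6 members set to gained passed in 20 of 20 simulations and one with none set in 0 of 20. Each simulated list was judged by its unadjusted p-value, and any of its members could be set to gained. Of the 172 real list members, 109 were marked in the wild type and could not gain. These simulations therefore do not show the power of the planned, adjusted test for gained genes. Alternatives used a −log10 q of at least 10, a fold of at least 3, other overlap rules (50% of both peaks, or summits within 200 bp), equal list lengths, other placements, other coverage limits (80% or 0%), merged domains, other windows and other edge distances. The software was python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.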

Results

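Chromatin immunoprecipitation with sequencing was carried out on unopened flowers of 5-week-old Arabidopsis thaliana plants. It mapped the binding sites of REF6 and the regions carrying trimethylation of lysine 27 on histone H3 (H3K27me3). REF6 is a Jumonji-type demethylase that removes H3K27me3, the mark of Polycomb-silenced genes, and it was precipitated through a GFP tag. The series held 23 samples in 10 groups, and 6 groups had a peak list. REF6-GFP in the ref6 mutant was profiled without DSG (3 samples) and with DSG, a crosslinker that joins proteins to each other (3 samples). REF6-ZnF-GFP was profiled with DSG in ref6 (3 samples) and in the elf6 ref6 jmj13 triple mutant (2 samples). H3K27me3 was profiled in the wild type (2 samples) and in the triple mutant (2 samples). For the REF6-ZnF samples in ref6, the titles name REF6-ZnF-GFP and the genotype entry names REF6-GFP, so the construct is given here as titled. The titles of the REF6-ZnF samples in the triple mutant name DSG, but the peak names of their list do not, unlike those of the other lists with DSG. Each list was made from the pooled samples of its group, so no value has a replicate error and no difference between lists has a replicate check. The read depth of the samples is not used here. Wilson 95% intervals below treat peaks or genes as independent and cover counting error only.

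The REF6-GFP lists held 5393 peaks with DSG and 4526 without it, covering 4.56 and 3.51 Mb. The REF6-ZnF-GFP lists held 332 peaks in ref6 and 9327 in the triple mutant, covering 0.300 and 5.24 Mb. The H3K27me3 lists held 7914 domains in the wild type and 9391 in the triple mutant, with median widths of 1724 and 1590 bp. The fold enrichment of each peak is the authors' own value and is used only to describe and rank peaks within a list. Its median was 4.37 for REF6-GFP with DSG, 4.22 without DSG, 2.03 for REF6-ZnF-GFP in ref6 and 3.10 for REF6-ZnF-GFP in the triple mutant. At a −log10 q of at least 10, all 5393 peaks of REF6-GFP with DSG were kept, against 85 REF6-ZnF-GFP peaks in ref6 and 3538 in the triple mutant.

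REF6-GFP summits lay mostly inside genes. With DSG, 85.9% of summits fell in the body of a protein-coding gene, against a mean of 54.3% over 1000 random placements of the peaks (exact position randomization, one-sided, p = 0.001, the smallest p that 1000 placements can give). A further 11.5% lay outside genes within 1 kb of one, and 2.65% lay farther away. Without DSG, 86.9% of summits fell in gene bodies, against 54.3% at random (exact position randomization, p = 0.001). For REF6-ZnF-GFP the share was 77.5% in the triple mutant, against 54.0% at random (exact position randomization, p = 0.001). In ref6 it was 55.7% against 53.5%, which did not pass the test (exact position randomization, p = 0.227), and at a −log10 q of at least 10 it fell below chance, to 31.8% against 51.9%.

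Among genes with a symbol, the highest REF6-GFP fold with DSG was 24.7, at ROL5 (AT2G44270; chromosome 2, 18299942 to 18301635, TAIR10) and at XTH12 (AT5G57530; chromosome 5, 23299572 to 23304190). XTH12 encodes a xyloglucan endotransglucosylase of the cell wall. The cytochrome P450 genes CYP71B2 and CYP71B28 shared 1 peak at chromosome 1, 4461315 to 4463327, with a fold of 24.5. The other genes among the leading 10, which had folds down to 23.4, were FNR2, which encodes a ferredoxin-NADP reductase of photosynthesis, the protein kinase gene SNRK2-8, DIN9, the cytosolic glutamine synthetase gene GSR 1, the phospholipase gene NPC3 and REF6 itself. All 10 also had a summit without DSG, where OCT6, ATCHX1, CSLC04, LDOX and PGR5-LIKE A joined the leading genes and OCT6 and ATCHX1 shared the highest fold, 31.9. The peak over the REF6 gene spanned 5939 bp (chromosome 3, 17934638 to 17940576) and ranked 2 by width in the list with DSG. The REF6 gene lay under a peak in all 4 REF6 lists, and these lines carried a REF6 transgene per the labels.

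Nearly every REF6-GFP peak found without DSG was also found with it. Of the 4526 peaks without DSG, 96.2% (95.6 to 96.7%) overlapped a peak with DSG, against 7.26% at random (exact position randomization, one-sided, p = 0.001). Of the 5393 peaks with DSG, 79.6% (78.5 to 80.7%) overlapped a peak without it, against 6.08% at random (exact position randomization, p = 0.001). The peaks with DSG that had no counterpart had low folds within their list. The 1098 such peaks had a median fold of 2.80, and the 4295 shared peaks had 5.29. When the list with DSG was split into 5 groups by fold, 35.6% of the peaks in the lowest group, 68.1% in the next and 94.5% in the middle group had a counterpart, as did 100% in both upper groups. The titles name separate input DNA for the samples with DSG and for those without it. Which input served as the control of each list is not given in the sources used here. Part of any overlap between lists, most readily between lists with DSG, may therefore come from a shared control.

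As deposited, the REF6-ZnF-GFP list of the triple mutant was the longest REF6 list. At a −log10 q of at least 10 it held 3538 peaks, against 5393 for REF6-GFP with DSG and 4438 without DSG. Peaks of the deposited REF6-ZnF list overlapped REF6-GFP sites more often than at random. Of its 9327 peaks, 22.9% (22.0 to 23.7%) overlapped a REF6-GFP peak with DSG, against 6.21% at random (exact position randomization, one-sided, p = 0.001). In the other direction, 37.99% (36.7 to 39.3%) of REF6-GFP peaks overlapped a REF6-ZnF peak, against 10.2% at random (exact position randomization, p = 0.001). This share was 54.7% on chromosomes 1 to 3, 15.1% on chromosome 4 and 9.82% on chromosome 5. The REF6-ZnF list held 52.3 peaks per 100 coding genes on chromosome 1, 47.9 on chromosome 2, 51.7 on chromosome 3, 9.64 on chromosome 4 and 4.58 on chromosome 5, whereas REF6-GFP with DSG held 16.8 to 21.0 on each. The leading gene was PTAC16 (AT3G46780), with a fold of 18.7 at chromosome 3, 17228415 to 17229904. It was followed by UCN, PRP39, CYSC1, SYP73, OMR1, AGO5, TET3, IAA20 and ABCB4, with folds down to 14.1. Of these 10 genes, 9 also had a REF6-GFP summit with DSG, the exception being the Argonaute gene AGO5.

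**Figure D1:**
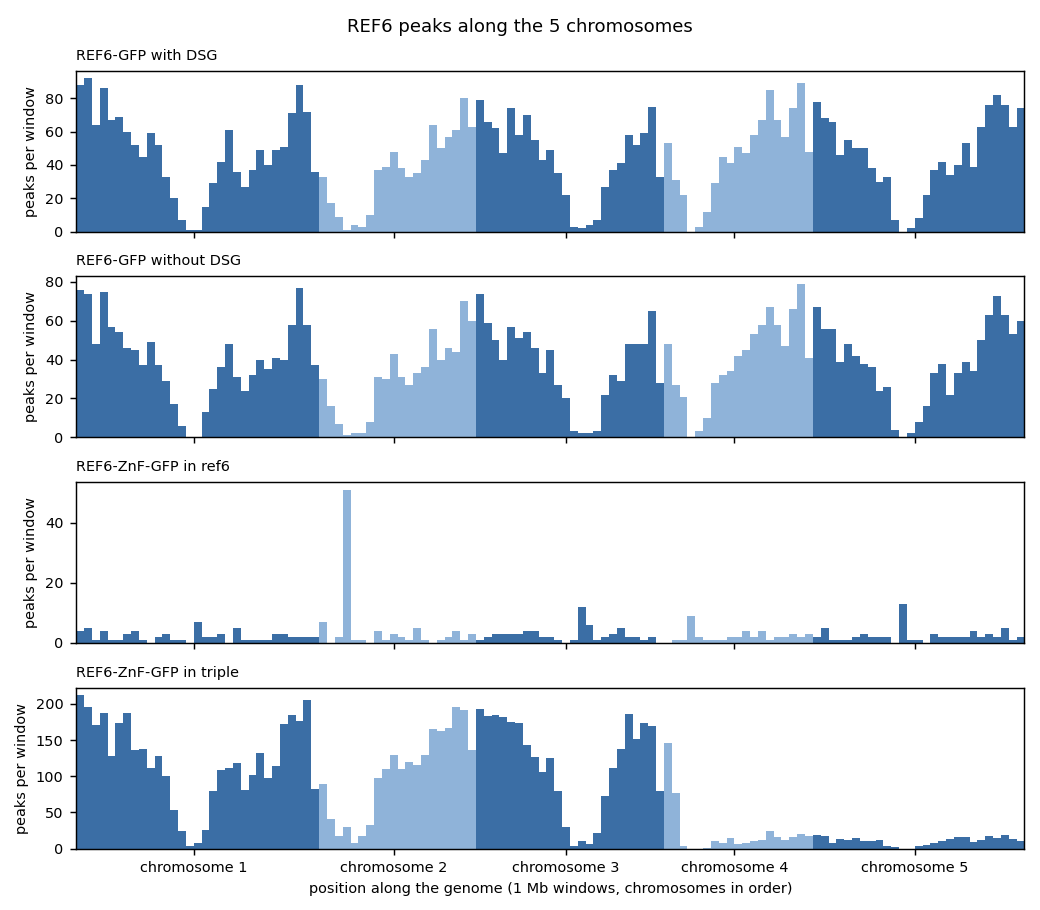
Number of REF6 peaks (y axis) in 1 Mb windows along the 5 chromosomes in order (x axis; the last window of each chromosome is shorter), with a panel for each of the 4 REF6 lists and alternating shades for chromosomes. The REF6-ZnF list in the triple mutant goes from 51.7 peaks per 100 coding genes on chromosome 3 to 9.64 on chromosome 4 and 4.58 on chromosome 5.

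REF6-ZnF-GFP in ref6 gave few peaks, and most of the covered length lay in 1 region. A block of 43 peaks between 3.2 and 3.6 Mb of chromosome 2 made up 75.2% of the length of this list. The leading genes were REF6 with a fold of 3.87, PFA-DSP5 with 3.01 and PRP39 with 2.599, followed by TRM82, RAB28 and PSAD-2 under 1 shared peak, HWI1, BXL1, CYSC1 and SYP73. All 10 also had a REF6-ZnF summit in the triple mutant, and 8 had a REF6-GFP summit with DSG. Of the 332 peaks, 48.2% (42.9 to 53.6%) overlapped a REF6-ZnF peak in the triple mutant, against 10.1% at random, and 16.6% (12.95 to 20.9%) overlapped a REF6-GFP peak with DSG, against 6.61% at random (exact position randomization, one-sided, p = 0.001 for each). With −log10 q of at least 10 in both lists, the overlap with REF6-GFP was below chance, at 3.53% of 85 peaks against 10.9% at random (exact position randomization, p = 0.998), and the overlap with REF6-ZnF in the triple mutant was 20.0% against 10.3% (p = 0.002). Without the chromosome 2 block and the REF6 gene, in a comparison added after the data were seen, 18.5% of 287 peaks overlapped REF6-GFP, against 4.90% at random, and 49.8% overlapped REF6-ZnF in the triple mutant, against 6.20% (exact position randomization, p = 0.001 for each).

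H3K27me3 covered more of the genome in triple mutant flowers than in wild-type flowers. It covered 20.9 Mb in the wild type and 23.3 Mb in the triple mutant. Of this, 17.2 Mb was shared, 3.71 Mb was covered in the wild type alone and 6.05 Mb in the triple mutant alone. Of the 9391 triple mutant domains, 2080 (22.1%) touched no wild-type domain, and they made up 41.8% of the length covered in the triple mutant alone. The other 3.52 Mb lay in domains that touched a wild-type domain. A REF6-GFP summit with DSG lay in 44.2% of the 2080 new domains, against 5.41% at random, and in 15.3% of the other 7311, against 11.7% at random (exact position randomization, one-sided, p = 0.001 for each). Of the 7914 wild-type domains, 929 (11.7%) touched no triple mutant domain, and 1 of these held a REF6-GFP summit. With the 7914 domains of highest −log10 q kept in each list this order reversed, as 1426 triple mutant domains (18.0%) and 1537 wild-type domains (19.4%) touched none in the other list, whereas the triple mutant still covered more length alone, 5.61 against 4.21 Mb. Domains without a counterpart had lower −log10 q within their list. The median was 6.24 for the new triple mutant domains against 28.2 for the others, and 1.82 for the 929 wild-type domains against 23.5 for the others.

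Among 27444 protein-coding genes, 1727 gained H3K27me3 in the triple mutant and 155 lost it. A gene gained the mark where less than 10% of its body was covered in the wild type and at least 50% in the triple mutant, and lost it in the reverse case. The leading gained genes with a symbol, by the fold of their domains, were STP11 (AT5G23270) and UGT75B2 (AT1G05530), followed by IPMI1, HCC2, the autophagy gene ATG8G, the photosystem II subunit gene PSBTN, STP2 (AT1G07340), NAC004, NAC005 and EDA12. STP11 and STP2 encode sugar transporters and went from 9.53% to 95.2% and from 0 to 99.7% coverage. UGT75B2, a glucosyltransferase gene, went from 0 to 91.9%. A REF6-GFP summit with DSG was found at 7 of these 10 genes. The leading lost genes were SCRL27 (AT5G45875), which went from 93.6% to 8.66% coverage, LCR22, the RALF-like peptide gene RALFL25, the hemoglobin gene HB2, RGF8, PEP7, the response regulator gene RR24, RTFL19, RALFL18 and SCRL10, and 0 of these 10 had a REF6-GFP summit. Lost genes had a median length of 736 bp and gained genes 1748 bp.

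The counts of gained and lost genes moved with the threshold on domains. With −log10 q of at least 10 required in the triple mutant list alone, 1364 genes gained and 831 lost the mark. With it required in the wild-type list alone, 2784 gained and 49 lost it, and with it required in both, 2083 gained and 362 lost it. With at least 80% coverage counted as marked, 1067 gained and 93 lost it. Of 39 gained genes named in this text, 21 kept the call under all 6 alternatives, and of 10 lost genes 2 did, RGF8 and RALFL25. The stricter limit in the wild type alone could not end a gained call, nor that in the triple mutant alone a lost call. For these calls the limit in both lists therefore repeated the limit in the other list alone. The gained calls of SNRK2-8, LDOX, CYP71B7, CSLC04, MAF2 and MAF3 ended with −log10 q of at least 10 in the triple mutant list, where their coverage was 0, and that of ABCB4 went from 50.9% to 46.4%.

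Genes that gained H3K27me3 were mostly REF6-bound. A REF6-GFP summit with DSG lay in or within 1 kb of 1190 of the 1727 gained genes, or 68.9% (66.7 to 71.0%), and of 24.4% of the 17722 other genes that were unmarked in the wild type. The gained genes with the strongest REF6-GFP peaks were XTH12, CYP71B2, CYP71B28, SNRK2-8, NPC3, FRK1, CYP707A3, LDOX, APT5 and CYP71B7. XTH12 went from 0 to 100% coverage. FRK1 (AT2G19190; peak at chromosome 2, 8326946 to 8329857), a receptor-like kinase gene induced by flagellin, also went from 0 to 100%. CYP707A3 (AT5G45340; chromosome 5, 18369021 to 18371296) encodes an abscisic acid hydroxylase and went from 0 to 56.9%. LDOX (AT4G22880; chromosome 4, 12005051 to 12006640) encodes an enzyme of anthocyanin synthesis and went from 0 to 54.8%.

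The odds ratio of REF6 binding between gained and other unmarked genes was 6.88, against a mean of 0.820 and a highest value of 1.02 over the random placements (exact position randomization, one-sided, p = 0.001). The bound share was 14.0% among genes marked in both genotypes and 22.2% among genes unmarked in both. Of the 155 lost genes 1 was bound, AT2G22805, named after its values were seen. Of the bound genes unmarked in the wild type, 21.6% gained the mark, against 3.85% of the unbound genes. This share was 12.4% (10.6 to 14.5%) in the lowest of 5 groups of bound genes by REF6-GFP fold and 38.4% (35.6 to 41.3%) in the highest. Comparisons with the REF6-ZnF list of the triple mutant on chromosomes 1 to 3 were added after the data were seen. A REF6-ZnF summit lay at 70.9% of gained genes, against 37.9% at random, and at 53.0% of genes unmarked in both genotypes, against 43.0% (exact position randomization, one-sided, p = 0.001 for each). The odds ratio of gain was 2.06 (bootstrap 95% interval 1.71 to 2.47) for this list and 6.12 (5.29 to 7.19) for REF6-GFP on the same chromosomes. Among genes without a REF6-GFP summit it was 1.86 (1.42 to 2.40) for REF6-ZnF, and among genes without a REF6-ZnF summit it was 7.90 (6.08 to 10.5) for REF6-GFP. REF6-ZnF peaks that overlapped no REF6-GFP peak gave 0.801, against 0.810 at random (exact position randomization, p = 0.547), but leaving out the shared peaks lowers this value by construction, since it took the summit from a larger share of gained genes (759 bound before and 423 after) than of the others.

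**Figure D2:**
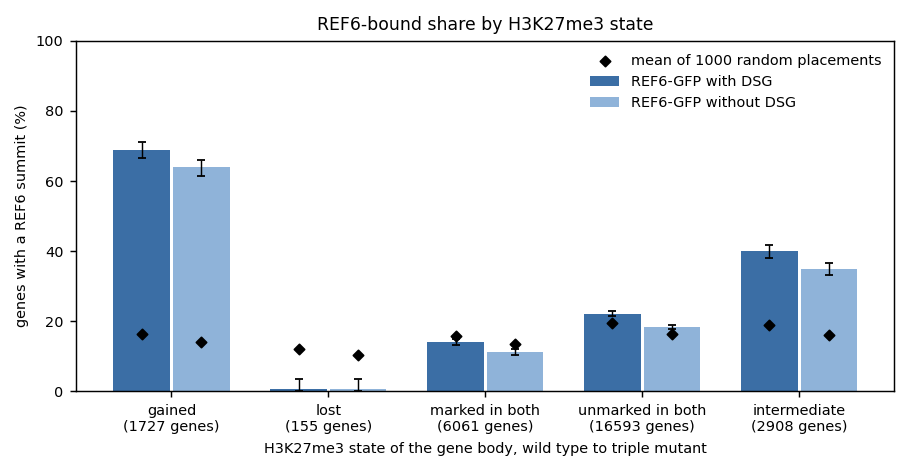
Share of genes with a REF6-GFP summit in the gene body or within 1 kb (y axis, percent) by H3K27me3 state from wild type to triple mutant (x axis), with DSG (dark bars) and without DSG (light bars). Error bars are Wilson 95% intervals and diamonds are means of 1000 random placements, and with DSG 68.9% of gained genes are bound against 16.5% at random.

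**Figure D3:**
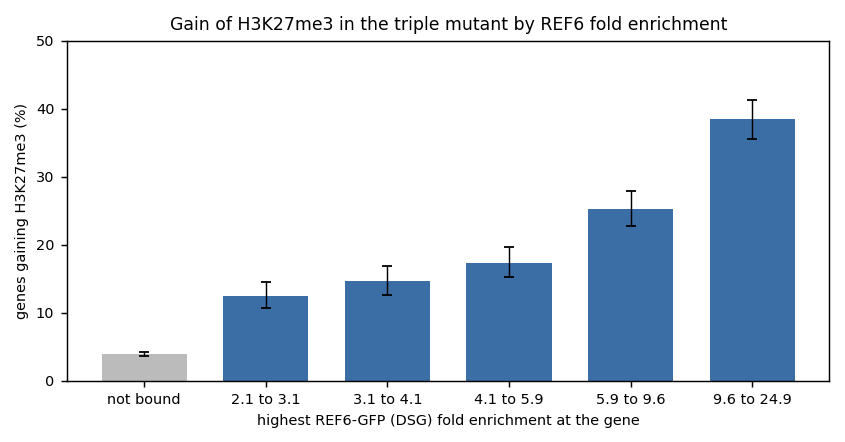
Share of genes unmarked in the wild type that gained H3K27me3 in the triple mutant (y axis, percent) by the highest REF6-GFP fold enrichment with DSG at the gene (x axis, unbound genes and 5 groups of bound genes), with Wilson 95% intervals as error bars. The share is 3.85% for unbound genes and 38.4% in the group with the highest folds.

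REF6-GFP summits were rare inside wild-type H3K27me3 domains and frequent in the regions marked in the triple mutant alone. With DSG, 7.34% (6.68 to 8.07%) lay inside a wild-type domain, against 17.6% at random (exact position randomization, lower tail, p = 0.001; this tail was added after the data were seen). A further 18.1% (17.1 to 19.1%) lay outside a domain within 1 kb of its edge, against 11.7% at random (exact position randomization, p = 0.001). Regions covered in the triple mutant alone held 36.3% (35.1 to 37.6%), against 5.12% at random (exact position randomization, p = 0.001). From the lowest to the highest of 5 fold groups, the share in these regions went from 25.02% to 54.0%, and the share inside wild-type domains went from 13.4% to 0.927%. For REF6-ZnF-GFP in the triple mutant on chromosomes 1 to 3, 20.2% of summits lay inside wild-type domains, against 17.9% at random, and 14.3% lay in regions marked in the triple mutant alone, against 5.09% (exact position randomization, one-sided, p = 0.001 for each).

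Regulators of flower development carried H3K27me3 in wild-type flowers. Of 20 floral organ identity and floral meristem genes, 19 were marked in the wild type, the exception being AP2, so only AP2 could gain the mark by the rule used here, and it did not. AG, AP1 and SEP3 were covered over 100% of their length in both genotypes. In 8 of 13 gene lists, more members were marked in the wild type than in 10000 random lists matched on gene length (exact randomization of list members, two-sided p = 0.0002, the smallest these lists can give, Benjamini-Hochberg adjusted p = 0.0013 for each). The other lists that passed were flowering time (12 of 18 marked), shoot meristem and organ boundary (14 of 17), leaf polarity (8 of 11), seed maturation and embryo (9 of 10), auxin biosynthesis and transport (15 of 20), TCP transcription factors (8 of 11) and root patterning (8 of 11), an organ that was not sampled. Gibberellin metabolism (7 of 14, adjusted p = 0.216) and anther and pollen development (6 of 11, adjusted p = 0.125) did not pass the exact randomization. Neither did Polycomb group genes (3 of 15, adjusted p = 0.947), H3K27 demethylases (0 of 5, adjusted p = 1) or housekeeping genes (0 of 9, adjusted p = 0.911 by exact randomization).

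Of the 172 members of these lists, 9 gained H3K27me3 and 0 lost it. No list passed the planned test for gained genes, but that test also counts members that could not gain, since 109 were marked in the wild type and only 51 were unmarked. In a test added after the data were seen, unmarked members were compared with random unmarked genes of the same length class, adjusted over the 13 lists. Flowering time (3 of 6 gained, exact randomization, adjusted p = 0.0156) and gibberellin metabolism (3 of 3, adjusted p = 0.0208) passed it. The flowering time result rests on the weaker domains, since MAF2 and MAF3 had 0% coverage at a −log10 q of at least 10 in the triple mutant list, which left FLM. The other 11 lists did not, and 8 of them had fewer than 5 unmarked members. The floral repressor genes FLM (AT1G77080), MAF2 (AT5G65050) and MAF3 (AT5G65060) went from 0 to 100%, 82.6% and 88.1% coverage, which made 3 of all 18 flowering time genes (planned exact randomization, adjusted p = 0.283). None of these 3 genes had a REF6-GFP summit, and MAF2 and MAF3 lie side by side, which the random lists do not allow for. The genes for the gibberellin-inactivating oxidases GA2OX1 (AT1G78440), GA2OX2 (AT1G30040) and GA2OX3 (AT2G34555) reached 100%, 90.3% and 66.1% coverage, which made 3 of all 14 gibberellin genes (planned exact randomization, adjusted p = 0.613). All 3 were REF6-bound, with folds of 17.9, 14.7 and 10.4. The auxin biosynthesis gene YUC3 (AT1G04610) went from 0 to 70.7% and was bound with a fold of 19.2. ABI5 (AT2G36270), of the abscisic acid response, went from 0 to 62.8% and VRN1 (AT3G18990) from 0 to 100%, both without a REF6-GFP summit. Their lists, auxin, seed maturation and Polycomb group, each had 1 gained gene (planned exact randomization, adjusted p = 1 for each), and the other 8 lists had 0 (adjusted p = 1 for each).

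Other list members had partial coverage in 1 or both genotypes and moved in both directions. The organ boundary gene CUC1 had 29.0% and 100% coverage and a REF6-GFP fold of 10.8, GA20OX1 had 31.9% and 97.9% with a fold of 8.88, and GA20OX2 had 43.2% and 100% with a fold of 13.04. Coverage fell without a REF6-GFP summit at PIN4 (89.3 to 42.0%), GA2OX8 (90.1 to 48.0%), FIS2 (68.6 to 28.9%), SMZ (56.6 to 19.5%), SEP4 (67.3 to 33.5%) and YUC6 (80.4 to 49.1%). It rose without one at FD (0 to 39.1%), ELF6 (0 to 23.6%), JMJ30 (0 to 21.1%) and EMF2 (0 to 16.9%). ELF6 is itself mutated in the triple mutant, so its change cannot be separated from the mutant allele. REV, TCP3 and TCP24 were REF6-bound, with folds of 17.6, 12.2 and 6.01, and had 0% coverage in both genotypes. In all, 29 list members were REF6-bound, and no list passed the test for bound genes, the lowest adjusted p being 0.287 for root patterning with 0 of 11. Bound genes numbered 8 of 20 in the auxin list, 6 of 14 in the gibberellin list, 3 of 11 TCP genes, 2 of 20 floral identity genes (SHP1 and SHP2), 2 of 18 flowering time genes (MAF4 and MAF5), 2 of 17 shoot meristem genes (CUC1 and CUC3) and 2 of 15 Polycomb group genes (RING1B and BMI1A). The leaf polarity, anther, demethylase and housekeeping lists had 1 each (REV, DYT1, REF6 and EF1A), and the seed maturation list had 0.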

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

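The comparisons on chromosomes 1 to 3, those without the chromosome 2 region and the REF6 gene, those of gain with REF6-ZnF peaks and that of unmarked list members were chosen only after the results were seen. Of the values of the comparisons under an alternative, 239 kept their direction and side of the threshold or stayed within the allowed range, 19 moved, 3 reversed and 2 newly passed. The 2 are the 3 gained flowering time genes and the 3 gained gibberellin genes, set against unmarked genes alone. Some of the 239 could not change, because the alternative did not act on the value. The binding window does not enter the counts of gained, lost or marked list members, and the coverage limit does not enter those of bound members. All 5393 peaks of REF6-GFP with DSG have a −log10 q of at least 10. Of the values of named genes, 249 stayed and 45 moved. Some of the 249 could not change either, such as those under the stricter limit in only the list where the gene was unmarked. At a −log10 q of at least 10 the lists held 85 (REF6-ZnF in ref6), 3538 (REF6-ZnF in the triple mutant), 4802 (wild-type H3K27me3) and 6062 (triple mutant H3K27me3) intervals, and at a fold of at least 3 they held 15, 5415, 2236 and 2476, since both limits remove weak intervals by construction. REF6-ZnF summits in ref6 reversed to 31.8% in genes, and their overlap with REF6-GFP reversed to 3.53%, at that −log10 q. Triple mutant domains touching no wild-type domain became 25.8% at that −log10 q and 18.0% with equal list lengths. Wild-type domains touching no triple mutant domain became 9.60% at that −log10 q, 9.74% after merging and 19.4% with equal list lengths, where the order of the 2 counts reversed. Gained genes became 1067 at 80% coverage and 2784 with the stricter limit in the wild type alone. Lost genes became 93 at 80% coverage, and 362, 831 and 49 with the stricter limit in both lists, in the triple mutant alone and in the wild type alone. The odds ratio of gain was 0.801 for REF6-ZnF peaks outside REF6-GFP sites, against 5.76 to 7.08 over the alternatives chosen beforehand, and leaving out peaks at REF6-GFP sites lowers it by construction. Except where a limit removes intervals by construction, the cause was not tested. No paired analysis was possible because each group has 1 pooled list, so neither a replicate block nor leaving out a replicate could be run. The motif alternatives and the promoter and untranslated region classes were not run, and windows upstream of genes were replaced by windows on both sides. Read depth, which limits how many weak sites a list holds, was not used here.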

Other observations

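All tests in this part were chosen only after the results were seen, except those of gene length and of weak domain calls. Gene families, formed from the letters of gene symbols, differed in how often their members gained H3K27me3 in the triple mutant. Among genes with a symbol that were unmarked in the wild type, 8.89% gained it, and 7 of 154 families exceeded this share after Benjamini-Hochberg adjustment. Cytochrome P450 genes gained it in 29 of 87 cases (33.3%, one-sided exact hypergeometric test, adjusted p = 1.99e-08), tau class glutathione transferases in 9 of 11 (81.8%, adjusted p = 1.19e-06), NAC transcription factors in 14 of 34 (41.2%, adjusted p = 1.68e-05) and expansins in 7 of 10 (70.0%, adjusted p = 0.000103). These 4 also passed when members within 20 genes of each other counted once, with adjusted p of 0.0128, 0.0247, 0.000169 and 0.00031. The cysteine-rich receptor-like kinase family CRK (13 of 28, adjusted p = 1.06e-05) and the glycosyltransferase family UGT (9 of 27, adjusted p = 0.00782) did not pass the exact test then, with adjusted p of 1 and 0.377.

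All 7 gained expansin genes were REF6-bound with DSG, as were 79.3% of the gained cytochrome P450 genes and 66.7% of the gained GSTU genes. Among all 1727 gained genes the share was 68.9%, and whether a family differed from it was not tested. EXPA1 went from 0 to 90.2% coverage and had a REF6-GFP fold of 17.2, and EXPA10 went from 0 to 87.6% with a fold of 15.7. GSTU19 and GSTU7 went from 0 to 100% and had no REF6-GFP summit.

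REF6-ZnF peaks in the triple mutant were few past 1.7 Mb of chromosome 4, a position fitted in 100 kb windows to give the strongest contrast. REF6-GFP peaks per gene past this point were 1.04 times those before it (95% interval 0.940 to 1.15), which argues against fewer REF6 sites there. Reads missing past one position from part of the pooled data are a candidate explanation, under which chromosome 5 and the rest of chromosome 4 would be alike: REF6-ZnF peaks per REF6-GFP peak on chromosome 5 were 1.04 times those on the rest of chromosome 4 (0.865 to 1.27). The ratio of triple mutant to wild-type H3K27me3 length past the point was 1.01 times that before it (0.9496 to 1.06), but fewer DNA copies in the REF6-ZnF plants cannot be told apart from missing reads, since the labels do not say that both sets of plants were 1 stock. No other biological explanation was tested.

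The REF6-ZnF list in ref6 had 43 peaks between 3247227 and 3509598 of chromosome 2, covering 226 kb. The REF6-GFP lists had 0 peaks in the region. This covers only the peaks kept in those lists, where 49.5% (with DSG) and 47.8% (without DSG) of the peak numbers remained. The REF6-ZnF list in the triple mutant had 26 peaks there, covering 13.5 kb. H3K27me3 had 39 domains there in the wild type (34.9 kb) and 4 in the triple mutant (2.33 kb). The median width of the peaks in ref6 was 15.1 times that of the others of the list (95% interval 10.9 to 23.6), but the region was picked for its wide peaks, so this value decides nothing. Extra DNA of this region in these libraries, from outside the nucleus or from other extra copies, therefore stays open. No biological explanation was tested.

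REF6-bound genes gained H3K27me3 more often than unbound genes. Gene length was tested as the cause with an odds ratio within length classes, which was 7.34 (95% interval 6.46 to 8.48) against 6.88 without classes. With −log10 q of at least 10 in all lists it was 5.76 (5.24 to 6.41), so the association was kept among strong calls. This limit also removed weak wild-type domains, and only 1364 of the 2083 genes gained under it were gained without it. The value therefore cannot decide on weak domain calls in the triple mutant list alone. On chromosomes 1 to 3 the odds ratio of a REF6-ZnF summit alone (1.86, 1.42 to 2.40) was 0.235 times that of a REF6-GFP summit alone (0.183 to 0.299). This argues against every peak marking such genes alike. The 2 lists were not matched on peak strength: the median −log10 q was 8.43 for REF6-ZnF in the triple mutant and 52.0 for REF6-GFP with DSG. Gain also rose with REF6-GFP fold, so the comparison cannot separate the protein from the strength of its peaks. A difference in read depth between the H3K27me3 lists and the loss of the 3 demethylases in the triple mutant stay open and were not tested.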
